A study of Homo sapiens with 136 samples.

How the data were processed

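RNA was sequenced from VCaP, an established prostate cancer cell line that responds to androgens and carries a TMPRSS2-ERG fusion. Per the labels' protocols, cells were kept in phenol-red-free medium with charcoal-stripped serum, given DMSO or the antiandrogen Casodex (bicalutamide) for 4 h, and then given ethanol or dihydrotestosterone (DHT) for 6 h. The labels describe 132 single cells and 4 libraries tagged 100k, 1 for each of the 4 treatments. They give no dose of either drug, name no replicate culture and do not give the tracking dye of each cell. The meaning of the 100k tag is not stated, so those libraries are called the 100k libraries here.

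The deposited values were FPKM, fragments scaled to gene length and library size, with 1 column per library in a single table of 57536 gene entries. Per the submitters' processing notes, reads were aligned with TopHat2 2.0.6 to GRCh37 (hg19). The program that made the FPKM values, its annotation and its filters were not stated. Entries with the same symbol and identifier were summed, which left 57424 genes, and all 136 columns were used. Gene symbols and Ensembl identifiers are those of the table. Gene types were taken by identifier, without its version, from a GENCODE annotation of a later genome build, so no coordinate is given. Of the 12928 genes analysed, 12516 matched to a type and 10496 were protein coding.

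The table holds no read counts, so the absolute depth of each library is unknown. The spacing of the lowest FPKM values gave the depth of the 100k libraries relative to the DMSO-ethanol one as 1.04 for DMSO-DHT, 1.27 for Casodex-ethanol and 1.27 for Casodex-DHT, the last from a weak peak of 2.90 times its surroundings. Genes at 1 FPKM or more were called detected. The mitochondrial share was the FPKM of the 13 mitochondrially encoded protein-coding genes as a percent of the sum, leaving out mitochondrial tRNA and rRNA genes.

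Genes were analysed if they reached 1 FPKM in at least 1 of the 100k libraries and in at least 10% of the cells of at least 1 group. Ratios were log2((FPKM+1)/(FPKM+1)) of the 100k libraries, or of the mean FPKM over the cells of each group, and every fold given is on that scale with its pseudocount of 1. The comparisons were DHT against ethanol after DMSO, DHT against ethanol after Casodex, Casodex against DMSO with ethanol and Casodex against DMSO with DHT. The difference of the DHT responses was the log2 ratio after DMSO minus that after Casodex. All DMSO cells carried the title prefix C1 and all Casodex cells the prefix C2, so in cells the pretreatment and the prefix are confounded. Each DHT comparison in cells lay within 1 prefix. Title S numbers up to 96 formed a separate block of 24 cells for each treatment, so any effect tied to them is confounded with treatment. Cells with numbers above 96 were not in such blocks.

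No test was made. Each treatment had 1 library of the 100k kind, and the cells of a treatment came from no named replicate culture, so each group counts as 1 sample and none of its values has a replicate check. No p-value, standard error or count of changed genes was made from cells. Standard deviations over cells describe the spread from cell to cell. Shares of cells at 1 FPKM or more are given with exact Clopper-Pearson 95% intervals, and a share of 0 with the limit that 3 counts allow. These cover counting error only, since the reads carried no molecular identifiers and the labels name no replicate culture.

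For 25 lists of genes, 402 symbols of which 401 were in the table, the median log2 ratio was set against 10000 random lists of the same size, matched on mean expression in 20 bins (seed 1). The percentile describes these libraries and is not a test. The lists covered androgen-induced and androgen-repressed genes, ERG and ETS targets, targets shared by steroid receptors, cholesterol and fatty acid synthesis, the unfolded protein response, polyamine synthesis, S phase, G2/M, immediate early and heat shock genes, NRF2, aryl hydrocarbon receptor and p53 targets, glycolysis, transcriptional coregulators, androgen metabolism, luminal, basal, neuroendocrine, fibroblast, immune and endothelial markers, ribosomal proteins, mitochondrially encoded genes and housekeeping genes. Lists share members, among others FKBP5 and TSC22D3 in the androgen-induced and the shared steroid list, ODC1 in the androgen-induced and polyamine lists, GAPDH and PGK1 in the glycolysis and housekeeping lists, NQO1 in the NRF2 and aryl hydrocarbon receptor lists, and UGT2B15 and UGT2B17 in the androgen-repressed and androgen metabolism lists. The androgen score of a cell was the mean of log2(FPKM+1) over the androgen-induced list. It was compared between groups as the percent of all pairs of cells in which the DHT cell was higher.

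Genes were named by a rule of size. Among the analysed genes with the same sign and at least 1.5-fold in both the 100k ratio and the ratio of cell means, genes were ranked by the smaller of their absolute log2 ratios, and the first 10 higher and the first 10 lower were named per comparison. KLK3, KLK2, TMPRSS2, FKBP5 and ERG were among the genes always named, with 2 to 4 members of each list where that many passed the filter. Some genes that met these rules are not reported here. The groups, comparisons, lists, naming rule and most alternatives were fixed before the data were examined. Short noncoding genes filled much of the named set, so after the values had been seen the same rule was also applied to protein-coding genes alone. That step named 5 genes per direction, a number lowered from 15 after the values and their dependence on the settings were known.

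The ratios, the naming rule and the list percentiles were tested on simulated data. The DMSO-DHT cells were split at random into a pair of parts and the DMSO-DHT 100k library was set against itself, over 12928 genes. Of 100 genes multiplied by 2 in 1 part and in 1 copy of the 100k library, 55.0% met the rule, and of 100 genes multiplied by 8, 89.0% did. The 100k ratio of these genes carried no noise, so these shares leave out noise between separate 100k libraries. Unchanged genes could not meet the rule, since their 100k ratio was 0 by construction, so false naming between separate 100k libraries was not tested. In cells alone, 51.1% of the unchanged genes were at least 1.5-fold apart between the parts. A list of 37 genes shifted by 1 on the log2 scale reached percentile 100, and 60 random lists had a median percentile of 48.4, with 8.33% of them under the 5th or over the 95th.

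The alternatives were pseudocounts of 0.1 and 5 FPKM, no filter and a filter of 5 FPKM with 25% of cells, rescaling each library to the same sum, and centring on the median gene. Those for cells were the mean of log2(FPKM+1), leaving out the highest cell of each group for each gene, leaving out cells below 3068 detected genes, which is 50 percent of the median, leaving out cells with a title S number above 96, and matching groups on detected genes. The score was also made from ranks and without KLK3, KLK2, TMPRSS2 and FKBP5, and shares at FPKM above 0 and of 5. Added after the data were seen were leaving out cells with a mitochondrial share above 50%, rescaling over nuclear protein-coding genes, and counting protein-coding genes only. Calculations used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.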

Results

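Single-cell and 100k RNA-seq libraries of VCaP cells were compared across 4 treatments to ask how the transcriptome of this androgen-responsive line differed with DHT, an androgen, and how a pretreatment with Casodex, an antiandrogen, altered that difference from cell to cell. There were 27 cells given DMSO and ethanol, 40 given DMSO and DHT, 37 given Casodex and ethanol, and 28 given Casodex and DHT. Each treatment also had 1 library tagged 100k. Values are FPKM. Since each treatment counts as 1 sample, no difference below has a replicate check, and differences describe these libraries.

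The number of genes at 1 FPKM or more ranged from 367 to 7615 per cell, with a median of 6136. Group medians were 6084 for DMSO-ethanol, 6207.5 for DMSO-DHT, 5752 for Casodex-ethanol and 6065.5 for Casodex-DHT. The 100k libraries had between 12458 and 12872 detected genes. Mitochondrial protein-coding genes held between 2.12% and 79.4% of the FPKM of a cell, against 2.94% to 4.00% in the 100k libraries. The median mitochondrial share was 24.0% in DMSO-ethanol cells, 13.6% in DMSO-DHT cells, 13.8% in Casodex-ethanol cells and 12.3% in Casodex-DHT cells. It exceeded 50% in 8, 3, 6 and 4 cells of these groups, in that order. The FPKM values of the 100k libraries summed to 914253 for DMSO-ethanol, 673823 for DMSO-DHT, 934794 for Casodex-ethanol and 802475 for Casodex-DHT, and those of single cells to between 423690 and 9092860. The mitochondrial tRNA gene MT-TL1 was the gene with the highest FPKM in 3 of the 4 100k libraries, with 7.96% to 18.6% of the sum.

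**Figure D1:**
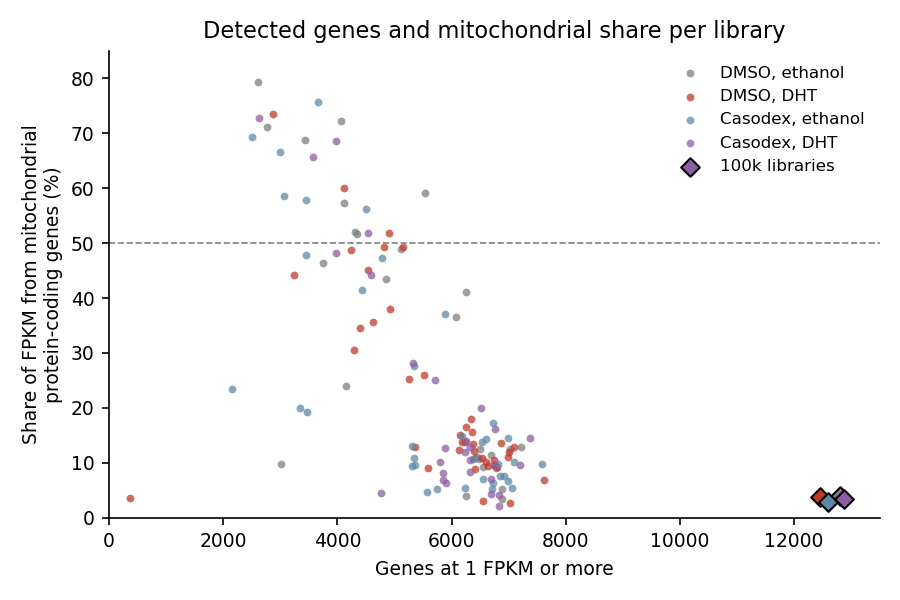
Number of genes at 1 FPKM or more (x axis) against the percent of FPKM from mitochondrial protein-coding genes (y axis), for the single cells (circles) and the 4 100k libraries (diamonds), coloured by treatment, with a dashed line at 50%. The 100k libraries lie between 12458 and 12872 genes and at 4.00% or less, and 21 of the cells lie above the line.

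Over all 12928 analysed genes, the median log2 ratio in the 100k libraries was −0.22 for DHT against ethanol after DMSO, 0.08 for DHT against ethanol after Casodex, −0.10 for Casodex against DMSO with ethanol and 0.21 for Casodex against DMSO with DHT. In cells it was 0.17, −0.01, 0.20 and 0.01, in the same order. The difference of the DHT responses had a median of −0.29 in the 100k libraries and 0.19 in cells. Ratios below are as computed from the deposited values and are to be read against these medians.

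With DHT after DMSO, 544 genes were at least 2-fold higher and 862 at least 2-fold lower than with ethanol in the 100k libraries. Of these, 299 and 506 were protein coding. The split depended on the scaling: it was 1072 higher and 500 lower with libraries rescaled to the same sum, 803 and 502 with ratios centred on the median gene, and 641 and 385 with rescaling over nuclear protein-coding genes. In the means over cells, 68.6% of the higher genes had the same direction, beside 58.7% of all genes that were higher there. Of the lower genes 55.5% had the same direction, beside 41.2% of all genes that were lower there. Across the 12928 genes, which are not independent replicates, the ratios of the 100k libraries and of the cell means had a Pearson correlation of 0.147.

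Among the protein-coding genes named by size, FKBP5 (ENSG00000096060.10) had 13.1 FPKM with ethanol and 376 with DHT in the 100k libraries, a log2 ratio of 4.73. In cells its mean was 4.47 ± 8.12 FPKM (SD over 27 cells) with ethanol and 93.2 ± 105.2 (SD over 40 cells) with DHT, a log2 ratio of 4.11. It reached 1 FPKM in 55.6% of ethanol cells (95% interval 35.3% to 74.5%) and in 95% of DHT cells (83.1% to 99.4%). That gap depended on the limit: the shares were 96.3% and 95% at FPKM above 0, and 29.6% and 80% at 5 FPKM. STEAP4 (ENSG00000127954.8) had 0.851 and 82.8 FPKM in the 100k libraries, with log2 ratios of 5.50 there and 3.69 in cells, or 4.36 in cells without the highest cell of each group. It was at 1 FPKM or more in 51.9% of ethanol cells (31.9% to 71.3%) and in 85% of DHT cells (70.2% to 94.3%), with 96.3% and 92.5% at FPKM above 0 and 11.1% and 60% at 5 FPKM. The log2 ratios of EAF2 (ENSG00000145088.4) were 3.87 in the 100k libraries and 4.70 in cells, and those of NCAPD3 (ENSG00000151503.8) were 3.99 and 3.66. CCDC141 (ENSG00000163492.9) had 0.186 and 14.5 FPKM in the 100k libraries. It reached 1 FPKM in 0 of 27 ethanol cells, which allows a share of up to 11.1%, and in 29 of 40 DHT cells, or 72.5% (56.1% to 85.4%). At FPKM above 0 the shares for CCDC141 were 33.3% and 87.5%. ORM2 (ENSG00000228278.2) was listed at 0 in the ethanol library and had 12.03 FPKM in the DHT library. It was seen at 1 FPKM or more in 7 of 40 DHT cells and is uncertain, since reads of its paralog ORM1 can be assigned to it. The other names of the fixed rule were RNU6-864P, RFPL3S and RP11-554L12.1, each listed at 0 in the ethanol 100k library, and LA16c-360H6.2, a gene whose cell ratio of 3.12 was 0.82 without the highest cell of each group.

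Of the genes lower with DHT after DMSO, IGFBP3 (ENSG00000146674.10) had 211 FPKM with ethanol and 20.3 with DHT in the 100k libraries, a log2 ratio of −3.31, and −2.27 in cells. It reached 1 FPKM in 85.2% of ethanol cells (66.3% to 95.8%) and in 47.5% of DHT cells (31.5% to 63.9%). SHH (ENSG00000164690.3) had log2 ratios of −2.66 in the 100k libraries and −3.92 in cells, GPR85 (ENSG00000164604.7) −2.67 and −2.73, HS3ST3B1 (ENSG00000125430.4) −3.03 and −2.45, and LUM (ENSG00000139329.4) −1.95 and −2.34. The antisense-type gene PCAT1 (ENSG00000253438.2) had −2.51 and −4.98, and its reads cannot be told from those of the opposite strand. The remaining names of the rule were AL391357.1, RP11-96H19.1, and AC016629.7, SNORA84 and SNORA58 (ENSG00000201129.1), the last 3 listed at 0 in the DHT 100k library. In cells, the ratios of RP11-96H19.1 and of that SNORA58 changed direction when cells with a mitochondrial share above 50% were left out.

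Of the genes that were always named, KLK3 (ENSG00000142515.10) had 9.39 FPKM with ethanol and 36.1 with DHT in the 100k libraries, a log2 ratio of 1.84, and 1.64 in cells, or 0.53 in cells after rescaling over nuclear protein-coding genes. KLK3 reached 1 FPKM in 14.8% of ethanol cells (4.19% to 33.7%) and in 45% of DHT cells (29.3% to 61.5%), with 25.9% and 55% at FPKM above 0. KLK2 (ENSG00000167751.8) was at 1 FPKM or more in every cell of the series, with log2 ratios of 0.54 and 0.84. KLK2 and KLK3 are paralogs, so reads could have been split between them. TMPRSS2 (ENSG00000184012.7) had log2 ratios of 1.53 in the 100k libraries and 0.87 in cells. The latter was 2.15 without the highest cell of each group and 0.30 after rescaling over nuclear protein-coding genes. ERG (ENSG00000157554.14) had 1.67 and 1.41. ERG reached 1 FPKM in 55.6% of ethanol cells and in 90% of DHT cells (76.3% to 97.2%), with 70.4% and 92.5% at FPKM above 0.

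The androgen-induced list, with 37 measured genes, had a median log2 ratio of 1.13 in the 100k libraries, above all matched random lists (percentile 100), and 0.88 in cells (percentile 100). In the 100k libraries 35 of the 37 genes were higher with DHT, 25 of them by at least 1.5-fold. TRPM8 (ENSG00000144481.12), among its most expressed members, had 118.7 FPKM with ethanol and 264.9 with DHT. The median of the 13 measured androgen-repressed genes was −0.97 in the 100k libraries (percentile 0) and −0.00 in cells (percentile 20.8). In that list MYC (ENSG00000136997.10) had 363 FPKM with ethanol and 71.5 with DHT in the 100k libraries, with log2 ratios of −2.33 there and −1.70 in cells, or −2.42 in cells without the highest cell of each group, and CAMK2N1 (ENSG00000162545.5) had −1.47 and −1.16. MYC reached 1 FPKM in 74.1% of ethanol cells (53.7% to 88.9%) and in 40% of DHT cells (24.9% to 56.7%). The 8 measured genes of the shared steroid receptor list, FKBP5 among them, had medians of 1.02 (percentile 99.99) and 0.71 (percentile 94.5), the latter 1.40 without the highest cell of each group. ZBTB16 (ENSG00000109906.9) had 14.9 and 80.2 FPKM in the 100k libraries, and HPGD (ENSG00000164120.9) had 144 and 194. The 17 genes of the unfolded protein response had medians of 0.20 (percentile 99.99) in the 100k libraries and 0.68 (percentile 99.6) in cells. HSPA5 (ENSG00000044574.7), in that list, had log2 ratios of 0.97 and 0.61, the latter −0.13 after rescaling over nuclear protein-coding genes.

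Per cell, the androgen score had a median of 2.89 (quartiles 2.28 and 3.15) in DMSO-ethanol cells and 4.09 (3.43 and 4.53) in DMSO-DHT cells. The DHT cell was higher in 87.6% of the pairs of a DHT cell and an ethanol cell. Of the 40 DHT cells, 26 lay above all 27 ethanol cells, 13 within their range and 35 above their median. The SD of the score over cells was 0.613 with ethanol and 0.871 with DHT. The DHT cells include 1 with only 367 detected genes and the lowest score, 0.940, which adds to their SD. FKBP5 and STEAP4 were both at 1 FPKM or more in 33 of the 40 DHT cells and in 9 of the 27 ethanol cells. An overlap beyond that given by their separate shares was not tested.

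**Figure D2:**
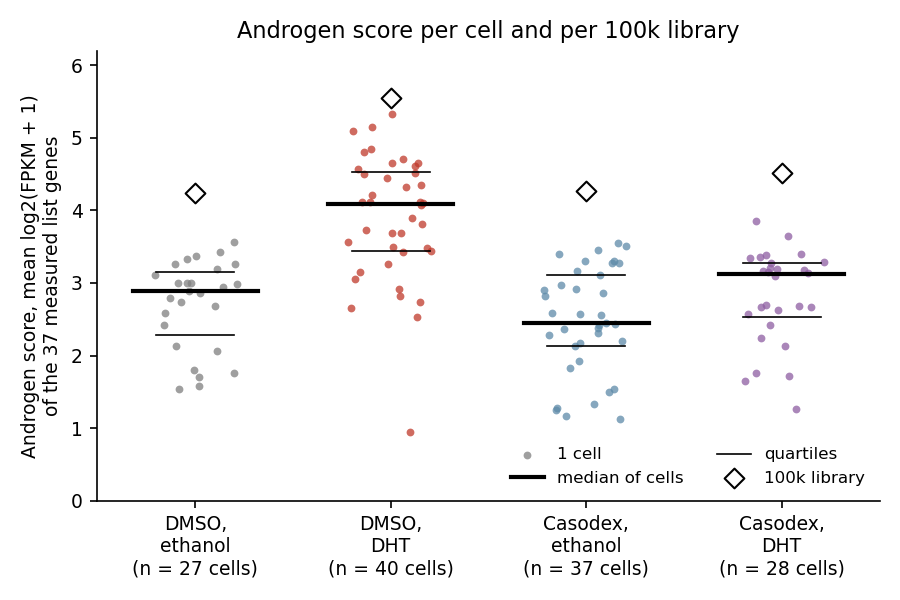
Androgen score (mean of log2(FPKM+1) over 37 androgen-induced genes, y axis) of each cell by treatment (x axis), with the median and quartiles of each group and the 100k library as a diamond. Medians are 2.89 in DMSO-ethanol, 4.09 in DMSO-DHT, 2.45 in Casodex-ethanol and 3.12 in Casodex-DHT cells, and the diamonds lie at 4.24, 5.55, 4.26 and 4.52.

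After Casodex, 415 genes were at least 2-fold higher and 279 at least 2-fold lower with DHT than with ethanol in the 100k libraries, of which 177 and 75 were protein coding. The split was 704 and 244 with libraries rescaled to the same sum, 350 and 329 centred on the median gene, and 336 and 190 after rescaling over nuclear protein-coding genes. Of the higher genes 47.95% had the same direction in the means over cells, where 49.6% of all genes were higher. Of the lower genes 54.1% had the same direction, where 50.3% of all genes were lower. The correlation across genes was 0.044. The androgen-induced list had a median of 0.27 in both assays, at percentile 99.99 in the 100k libraries and 98.9 in cells. In the 100k libraries 28 of its 37 genes were higher with DHT, 4 of them by at least 1.5-fold. FKBP5 had 17.2 FPKM with ethanol and 23.6 with DHT, a log2 ratio of 0.43 in the 100k libraries. Its ratio of 0.82 in cells was −0.26 in cells matched on detected genes, and it reached 1 FPKM in 24.3% of ethanol cells (11.8% to 41.2%) and in 32.1% of DHT cells (15.9% to 52.4%), with 59.5% and 67.9% at FPKM above 0. STEAP4 had 0.742 and 1.44 FPKM in the 100k libraries, and EAF2 19.1 and 17.98. KLK3 had 12.8 and 15.6 FPKM there, a log2 ratio of 0.27, and 1.80 in cells, where 1 DHT cell held 409 FPKM and the ratio was 0.82 without the highest cell of each group. Over the scalings tried it ranged from 0.45 to 4.02. TMPRSS2 had log2 ratios of 0.48 and 0.44. KLK2 had 0.06 in the 100k libraries, or −0.02 centred on the median gene, and 0.20 in cells. ERG had 1.12 and −0.13, the latter 0.03 with libraries rescaled to the same sum. MYC had 380 and 374 FPKM in the 100k libraries. The shared steroid receptor list had medians of 0.42 (percentile 98.6) and 0.74 (percentile 99.3), and the androgen-repressed list −0.10, or 0.11 with libraries rescaled to the same sum, and −0.24.

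Per cell, the androgen score after Casodex had a median of 2.45 (quartiles 2.13 and 3.11) with ethanol and 3.12 (2.53 and 3.28) with DHT, and the DHT cell was higher in 63.7% of the pairs. Of the 28 DHT cells, 2 lay above all 37 ethanol cells, 26 within their range and 21 above their median. The SD was 0.731 with ethanol and 0.654 with DHT. FKBP5 and STEAP4 were both at 1 FPKM or more in 1 of the 28 DHT cells.

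The genes named by size for DHT after Casodex were mostly short or noncoding. Those higher were RP11-848P1.7, SNORD17, RP11-98F14.11, SNORA47, RP11-379F4.6, MIR3661, AL603831.1 and HMGN1P3, all listed at 0 in the ethanol 100k library, with SIPA1L1 and CTC-228N24.3. Those lower were RNU4-46P, SNORA18, ENSG00000266341.1, AC110615.1, SNORA46, SNORA58 (ENSG00000249020.1), SNORA79, AC090602.2, VTRNA1-3 and RP11-436H11.4. Among protein-coding genes, SIPA1L1 (ENSG00000197555.5) had log2 ratios of 2.02 in the 100k libraries and 2.01 in cells, the latter −0.04 without the cells with a mitochondrial share above 50% and 0.30 without the highest cell of each group. CCDC175 (ENSG00000151838.7) had 2.21 and 1.63, DNAH8 (ENSG00000124721.13) 1.64 and 1.37, or 0.74 in cells without the highest cell of each group, LCORL (ENSG00000178177.9) 1.33 and 1.54, and ALPK1 (ENSG00000073331.13) 1.31 and 1.61. Of the lower ones, NPM2 (ENSG00000158806.9) had −1.45 and −1.36, the latter 3.35 without cells with a title S number above 96. SVOP (ENSG00000166111.5) had −1.34 and −2.32, and POP1 (ENSG00000104356.6) −1.19 and −2.39, with −0.17 and −1.67 in cells for these genes without the highest cell of each group. DNLZ (ENSG00000213221.4) and C4orf48 (ENSG00000243449.2) were listed at 0 in the Casodex-DHT 100k library.

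**Figure D3:**
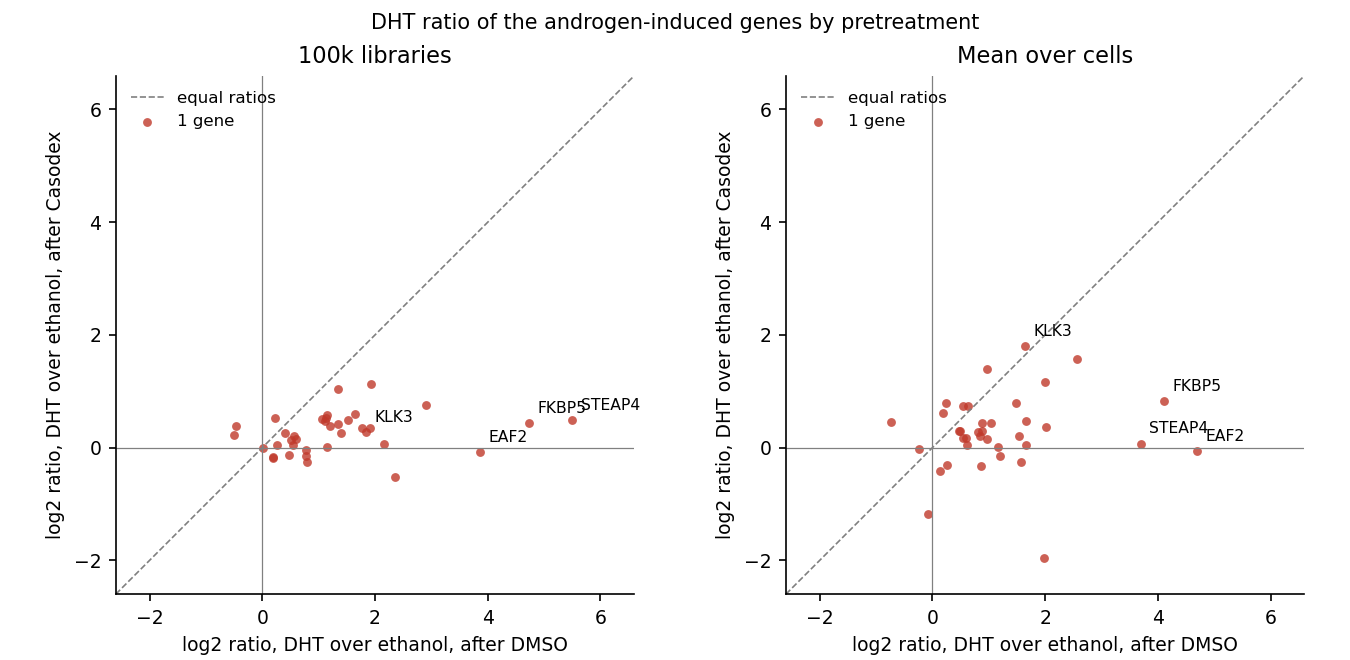
Log2 ratio of DHT against ethanol after DMSO (x axis) and after Casodex (y axis) for the 37 androgen-induced genes, in the 100k libraries (left) and in the means over cells (right), with a dashed line where both are equal. List medians are 1.13 after DMSO and 0.27 after Casodex in the 100k libraries, and 0.88 and 0.27 in cells, and no scaling tried changed the sign of these medians.

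The DHT responses after DMSO and after Casodex, which share no library, differed by a median of 0.81 over the androgen-induced list in the 100k libraries (percentile 100) and of 0.61 in cells (percentile 98.5). This difference was not tested. It was 4.30 in the 100k libraries and 3.28 in cells for FKBP5, 5.01 and 3.62 for STEAP4, 3.94 and 4.76 for EAF2, and 3.84 and 4.89 for NCAPD3. In cells it was 4.02 for FKBP5, 4.46 for STEAP4 and 5.68 for EAF2 without the highest cell of each group. KLK3 had 1.57 and −0.16. The latter was −1.88 with libraries rescaled to the same sum, 0.08 after rescaling over nuclear protein-coding genes and 1.16 without the highest cell of each group. TMPRSS2 had 1.05 and 0.43, and in cells these same settings gave 1.1995, −0.31 and 1.73. KLK2 had 0.49 and 0.64, and ERG 0.55 and 1.54. The shared steroid receptor list had medians of 0.80 and 0.55, and the androgen-repressed list −0.83 and 0.05, the latter −0.10 with libraries rescaled to the same sum. Over all genes, 705 differences were at least 1 on the log2 scale and 1734 were −1 or less in the 100k libraries. That split was 947 and 1380 with libraries rescaled to the same sum, 1064 and 924 centred on the median gene, and 731 and 998 after rescaling over nuclear protein-coding genes. The correlation of these differences across genes between the assays was 0.101. Lowest among protein-coding genes by the naming rule were SIPA1L1 (−3.13 and −3.15), VAV3 (ENSG00000134215.11; −2.98 and −2.77), ZFP36L2 (ENSG00000152518.5; −3.03 and −2.77), SHH (−2.50 and −3.82) and HS3ST3B1 (−2.68 and −2.47). On the higher side, SVOP had 4.03 and 6.69. Leaving out the highest cell of each group gave −1.64 in cells for SIPA1L1, −1.14 for HS3ST3B1 and 0.58 for SVOP. ORM2 was listed at 0 in 3 of the 4 treatments. The other names of the rule were SCARNA9, RNU6-864P, SNORA37, RFPL3S, HIST1H1PS1, AL109927.1 and RNU4-46P on the higher side, and SNORA47, MIR3661, RP11-415I12.3, RNU1-67P, RP3-462D8.2 and RP4-669P10.19 on the lower side.

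With DHT present, Casodex against DMSO gave 877 genes at least 2-fold higher and 483 at least 2-fold lower in the 100k libraries, of which 527 and 263 were protein coding. The split was 692 and 754 with libraries rescaled to the same sum, 511 and 702 centred on the median gene, and 513 and 490 after rescaling over nuclear protein-coding genes. In the cell means, where 50.8% of all genes were higher and 49.2% lower, 61.3% of the higher and 67.1% of the lower genes had the same direction, and the correlation across genes was 0.196. This comparison shares the DMSO-DHT libraries with that of DHT against ethanol after DMSO, so the 2 sets of values are not independent, and in cells it is confounded with the title prefix. The androgen-induced list had medians of −0.66 in the 100k libraries and −0.85 in cells, both at percentile 0. In the 100k libraries 2 of its 37 genes were higher with Casodex, and 22 were lower by at least 1.5-fold. Log2 ratios were −3.94 in the 100k libraries and −3.80 in cells for FKBP5, −5.10 and −4.91 for STEAP4, −3.44 and −5.44 for NCAPD3, −3.50 and −3.43 for EAF2, and −3.42 and −3.07 for CCDC141. Leaving out the highest cell of each group gave −4.60 in cells for FKBP5, −4.28 for EAF2 and −3.78 for CCDC141. TMPRSS2 had −0.93 and −2.50, ERG −1.16 and −1.90, and KLK2 −0.18 and −0.55. KLK3 had −1.16 in the 100k libraries and 0.60 in cells, and the latter was −1.75 without the highest cell of each group. On the higher side, SHH had 2.42 and 5.54, MYC 2.37 and 2.28, HS3ST3B1 2.40 and 2.25, GPR85 2.36 and 2.23, and VAV3 2.16 and 3.34, with 4.95 for SHH, 3.06 for MYC and 1.201 for HS3ST3B1 in cells without the highest cell of each group. The remaining names were MIR421, SNORA71A, RNU1-67P, RP11-98F14.11, RNU1-59P, AL603831.1, MIR3661 and AC022201.5, all listed at 0 in the DMSO-DHT 100k library, with RP11-662M24.2 on the higher side, and SCARNA9, ORM2, RP11-554L12.1, AC068706.2 and LA16c-360H6.2 on the lower side. None of the 28 Casodex-DHT cells had an androgen score above the median of the 40 DMSO-DHT cells, and the Casodex cell was higher in 14.5% of the pairs.

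**Figure D4:**
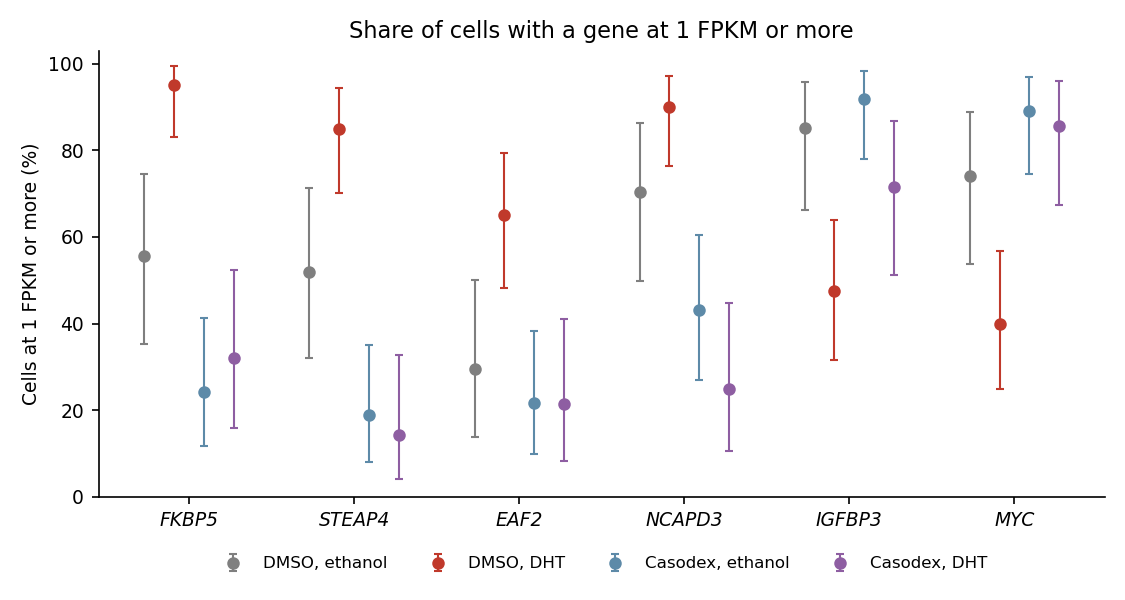
Share of cells at 1 FPKM or more (y axis, percent) with exact 95% binomial intervals, for FKBP5, STEAP4, EAF2, NCAPD3, IGFBP3 and MYC (x axis) in the 4 treatments. FKBP5 reached 55.6%, 95%, 24.3% and 32.1%, and MYC 74.1%, 40%, 89.2% and 85.7%, of DMSO-ethanol, DMSO-DHT, Casodex-ethanol and Casodex-DHT cells.

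With ethanol, Casodex against DMSO gave 393 genes at least 2-fold higher and 434 at least 2-fold lower in the 100k libraries, of which 158 and 189 were protein coding. The split was 394 and 478 with libraries rescaled to the same sum, 471 and 344 centred on the median gene, and 297 and 257 after rescaling over nuclear protein-coding genes. The same direction was found in the cell means for 59.03% of the higher and 41.5% of the lower genes. There, 60.5% of all genes were higher and 39.4% were lower. The correlation across genes was 0.003. This comparison is also confounded with the title prefix in cells. It shares the DMSO-ethanol libraries with DHT against ethanol after DMSO, and the Casodex-ethanol libraries with DHT against ethanol after Casodex. The values are thus not independent of those comparisons. SVOP and NPM2, among others, were named as lower with DHT after Casodex and as higher here from the same Casodex-ethanol values. The androgen-induced list had medians of 0.05 in the 100k libraries (percentile 99.33) and −0.01 in cells (percentile 4.86), the latter 0.07 with libraries rescaled to the same sum. FKBP5 had log2 ratios of 0.36 and −0.51, and TMPRSS2 0.12 and −2.07. In TMPRSS2, 1 DMSO-ethanol cell held 319 FPKM, and the cell ratio was −1.07 without the highest cell of each group. KLK3 had 0.40 and 0.44, the latter −0.41 with libraries rescaled to the same sum and −0.58 without the highest cell of each group. KLK2 had 0.31 and 0.09, the latter −0.11 centred on the median gene. ERG had −0.62 and −0.36, the latter 0.12 without the highest cell of each group. In the 100k libraries the 25 G2/M genes had a median of −0.93 (percentile 0), and the 14 immediate early and heat shock genes had −0.75 (percentile 0). In cells these medians were 0.44 and 0.04, which became −0.05 and −0.15 after rescaling over nuclear protein-coding genes. FOS (ENSG00000170345.5) had 199.5 FPKM with DMSO and 84.8 with Casodex in the 100k libraries. The shared steroid receptor list had medians of −0.45 (percentile 1.07) and −0.73 (percentile 0.50), and the 13 mitochondrially encoded genes −0.58 and −0.49, both at percentile 0. Protein-coding genes named as higher were SVOP (1.53 and 2.58), HSF2BP (ENSG00000160207.4; 1.47 and 2.18), NPM2 (1.45 and 1.77), HDAC11 (ENSG00000163517.10; 1.42 and 2.32) and ZGPAT (ENSG00000197114.6; 1.42 and 1.59). The cell ratios were 0.20 for SVOP, 1.13 for HSF2BP and 0.25 for ZGPAT without the highest cell of each group, and −2.90 for NPM2 without cells with a title S number above 96. ZGPAT reached 1 FPKM in 2 of 37 Casodex and 1 of 27 DMSO cells. Among those lower were KAT8 (ENSG00000103510.15; −1.51 and −2.09), COG3 (ENSG00000136152.10; −1.51 and −2.03), FAM177B (ENSG00000197520.6; −1.48 and −2.27) and SVIL (ENSG00000197321.10; −2.49 and −1.30). COG3 had 0.05 in cells without those below 3068 detected genes. Without the highest cell of each group, the cell ratios were −0.38 for COG3 and −1.30 for FAM177B, and KAT8 had −0.12 without cells with a mitochondrial share above 50%. The remaining names were SNORA37, RFPL3S, ENSG00000266341.1, AL353898.3, SNORA18, RNU6-864P, AC018865.8, AL109927.1, AC018630.1 and HIST1H1PS1 as higher, and RP11-415I12.3, SNORD17, AC010761.10, AC018816.3, HIST1H2BE, SRSF8, AC006262.5 and CTD-2196E14.4 as lower.

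The other lists were read for DHT against ethanol after DMSO, where the median gene was at −0.22 in the 100k libraries and 0.17 in cells. The G2/M list had medians of −0.20 in the 100k libraries, or 0.21 with libraries rescaled to the same sum, and 2.24 in cells (percentile 100). The latter was 0.22 without the 3 cells of each group with the highest G2/M score, and in DMSO-DHT cells those 3 held 86.3% of the G2/M FPKM. CCNB1 (ENSG00000134057.10), in that list, had 67.3 FPKM with ethanol and 63.2 with DHT in the 100k libraries, UBE2C (ENSG00000175063.12) 52.8 and 42.1, and TOP2A (ENSG00000131747.10) 38.2 and 36.7. The 34 ribosomal protein genes, RPS27, RPS19 and RPS18 the most expressed, had −0.47 (percentile 0.10) and 0.24. The FPKM sums of the 100k libraries were 914253 with ethanol and 673823 with DHT after DMSO, so rescaling raised the lists together. MT-TL1, at 100557 and 0 FPKM in these libraries, made up part of that gap. Reversals of sign are thus 1 shared shift, not a separate change of each list. In the 100k libraries the sign of the following medians was reversed by rescaling to the same sum, whose value is given after each. They were −0.07 and 0.36 for ERG and ETS targets (CRISP3, PLA1A, HDAC1), −0.06 and 0.33 for cholesterol and fatty acid synthesis (SC5D, MSMO1), −0.07 and 0.37 for polyamine synthesis (AMD1, OAZ1, SAT1), −0.30 and 0.08 for S phase (RPA2, PCNA, MCM7), and −0.15 and 0.23 for immediate early and heat shock genes (HSPE1, HSPD1, FOS). They were also −0.24 and 0.10 for NRF2 targets (TXN, TXNRD1, PGD), −0.42 and 0.02 for glycolysis (GAPDH, TPI1, ENO1), −0.41 and 0.02 for transcriptional coregulators (HSP90AB1, HSP90AA1, NCOA4), and −0.40 and 0.04 for luminal markers (KRT8, FOLH1, KRT18). The remaining ones were −0.10 and 0.16 for neuroendocrine markers (SCG3, CHGB, ENO2), −0.38 and 0.06 for mitochondrially encoded genes (MT-CO2, MT-ATP8, MT-CO3), and −0.33 and 0.10 for housekeeping genes (EEF1A1, GAPDH, PPIA). FOLH1 (ENSG00000086205.12) had 304.6 FPKM with ethanol and 139.5 with DHT in the 100k libraries.

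In cells the mitochondrially encoded genes had a median of −0.72 (percentile 0). Aryl hydrocarbon receptor targets (CYP1A1, NQO1, TIPARP; 4 genes) had medians of 0.11 in the 100k libraries and 0.63 in cells. The 7 p53 targets (CDKN1A, BTG2, MDM2 and others) had −0.45 and −0.09, the latter 0.14 with libraries rescaled to the same sum, and the 11 androgen metabolism genes (HSD17B4, HSD17B11, AKR1C3 and others) −0.34 and 0.28. Of the 9 basal markers only DST was measured, with 0.29 and −0.32, and of the 9 fibroblast markers only LUM, given above. None of the 10 immune and 6 endothelial markers passed the expression filter.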

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

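The comparison given here was chosen after the values had been seen, and it covers the protein-coding genes named in the report. Of these, 3 had log2 ratios of DHT against ethanol that were at least 1.5-fold in one direction after DMSO and at least 1.5-fold in the other after Casodex, in both the 100k libraries and the cell means. All 3 were also named for the size of the difference between these responses, so their opposite directions follow in part from that selection. The difference between the responses was not tested for any of them, and with 1 sample per treatment there is no replicate check.

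SVOP had ratios of 2.69 in the 100k libraries and 4.37 in cells after DMSO, and −1.34 and −2.32 after Casodex, so that the responses differed by 4.03 in the 100k libraries. Few cells carried it: it reached 1 FPKM in 0 DMSO-ethanol, 4 DMSO-DHT, 4 Casodex-ethanol and 1 Casodex-DHT cells, and 1 DMSO-DHT cell held 846 FPKM. Without the highest cell of each group the ratio in cells after Casodex was −0.17 and the difference in cells was 0.58 in place of 6.69.

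SIPA1L1 had ratios of −1.10 and −1.14 after DMSO and 2.02 and 2.01 after Casodex, a difference of −3.13 in the 100k libraries. Its ratio in cells after Casodex was 0.30 without the highest cell of each group and −0.04 without cells whose mitochondrial share exceeded 50%.

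ZFP36L2 had ratios of −2.40 and −1.40 after DMSO and 0.63 and 1.36 after Casodex, a difference of −3.03. Its 100k ratio after Casodex lay close to the 1.5-fold limit, and the median gene was at 0.08 there. No technical or biological explanation was tested for these 3 genes.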

How the results depend on the processing

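Leaving out cells with a mitochondrial share above 50%, rescaling over nuclear protein-coding genes, and counting protein-coding genes only were chosen after the data were seen. The limit for a moved ratio, 1.5-fold, was a choice made because no replicate spread exists. A reversal was counted only where the reported ratio was at least 1.5-fold. No paired analysis was possible because the values come from no test, and the replicate numbers follow the order of deposition. Read depth is unknown, which leaves open how much of the spread among genes of low FPKM is sampling.

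The androgen-induced list kept its direction under all alternatives tried in 4 of the 5 comparisons. After DMSO the median for DHT against ethanol ranged from 0.76 to 1.54 over 7 alternatives in the 100k libraries and from 0.67 to 1.36 over 13 in cells. After Casodex it ranged from 0.19 to 0.47 and from 0.14 to 0.40, for Casodex against DMSO with DHT from −0.91 to −0.55 and from −0.96 to −0.61, and for the difference of the responses from 0.53 to 1.10 and from 0.42 to 1.01. With ethanol, Casodex against DMSO ranged from 0.02 to 0.14 in the 100k libraries and from −0.28 to 0.07 in cells. The percent of pairs with a higher androgen score in the DHT cell ranged from 82.2 to 93.9 after DMSO and from 57.1 to 69.8 after Casodex, over 8 alternatives. Of the values that answer a comparison, 47 moved past the limits and the rest did not. Of the others, 8418 stayed within the limits, 1080 moved and 54 reversed. Reversals were found only among values over cells. Several alternatives were applied to cells alone. In the 100k libraries a pseudocount cannot change the sign of a gene's ratio, and rescaling or centring shifts ratios together. The lack of reversals there therefore says little about how robust the 100k values are.

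All 47 were counts of genes at least 2-fold apart in the 100k libraries, given as higher and lower. For DHT against ethanol after DMSO they were 860 and 1597 with a pseudocount of 0.1 FPKM, 205 and 212 with 5 FPKM, 204 and 311 with the stricter filter, and 299 and 506 for protein-coding genes. Higher genes numbered 969 without a filter, and rescaling to the same sum gave 1072 and 500. Lower genes numbered 502 centred on the median gene and 385 rescaled over nuclear protein-coding genes. For DHT against ethanol after Casodex the counts were 914 and 557, 81 and 70, 1.1e+02 (rounded) and 76, and 177 and 75 in the first 4 of these settings, 710 and 579 without a filter, and 704 higher rescaled to the same sum. For Casodex against DMSO with ethanol they were 737 and 909, 88 and 88, 1.1e+02 and 1.1e+02 (rounded), 158 and 189, 682 and 756 without a filter, and 257 lower rescaled over nuclear protein-coding genes. For Casodex against DMSO with DHT they were 1638 and 785, 179 and 172, 311 and 167, 527 and 263, 922 lower without a filter, 754 lower rescaled to the same sum, and 511 and 513 higher when centred and when rescaled over nuclear protein-coding genes. The stricter filter and the limit to protein-coding genes lower the counts by leaving out genes. Using no filter raises them by adding genes. A larger pseudocount shrinks the ratios of genes of low FPKM and a smaller one widens them. Rescaling and centring shift ratios together.

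The reversed values follow by setting, each a log2 ratio in cells. Apart from RP11-848P1.7 the cause was not tested. That gene was counted as reversed where its ratio became 0, so it vanished and did not change direction. Leaving out cells below 3068 detected genes gave, for Casodex against DMSO with ethanol, COG3 0.048, CTD-2196E14.4 2.46 and RPA2 0.12, and for the difference of the responses RPA2 0.38. Leaving out cells with a mitochondrial share above 50% gave −0.10 for the polyamine list in Casodex against DMSO with ethanol, in place of 0.76. It gave −0.036 for SIPA1L1 with DHT after Casodex, 0.81 for RP11-96H19.1 and 0.59 for SNORA58 (ENSG00000201129.1) with DHT after DMSO, and 0.30 for the difference of RP11-415I12.3.

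Leaving out cells with a title S number above 96 gave, for Casodex against DMSO with DHT, AC068706.2 3.72, LA16c-360H6.2 0.29 and SCARNA9 1.22. With ethanol it gave AC018630.1 −1.81, AL109927.1 −1.08, CTD-2196E14.4 2.70, NPM2 −2.90, SNORA18 −1.03 and RPA2 0.48. For DHT after Casodex it gave NPM2 3.35, RNU4-46P 0.30, SNORA18 0.78, VTRNA1-3 0.89 and RP11-848P1.7 0, since the single cell with that gene was left out. For the difference it gave RNU4-46P −0.54, SCARNA9 −1.06 and RPA2 0.83. Matching on detected genes gave LA16c-360H6.2 0.27 for Casodex against DMSO with DHT, FKBP5 −0.26 for DHT after Casodex and SNORA37 −0.27 for the difference.

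The mean of log2(FPKM+1) over cells gave KLK3 −0.76 and DST −0.0018 for Casodex against DMSO with DHT. With ethanol it gave AL109927.1 −0.25, NPM2 −0.11, RNU6-864P −0.021, SNORA18 −0.11, CCNB1 −0.29, RPA2 0.16, TOP2A −0.66, UBE2C −0.17 and ZBTB16 −0.044. For DHT after Casodex it gave NPM2 0.23 and SNORA18 0.20, and for the difference AKR1C3 −0.019 and RPA2 0.29. Rescaling over nuclear protein-coding genes gave CCNB1 −0.15 for Casodex against DMSO with ethanol and HSPA5 −0.13 for DHT after DMSO. Leaving out the highest cell of each group gave KLK3 −1.75 for Casodex against DMSO with DHT, and AL109927.1 −1.02, CTD-2196E14.4 1.11 and UBE2C −0.37 with ethanol. It gave AC110615.1 0.14 and RP11-848P1.7 0 for DHT after Casodex, RP11-96H19.1 0.21 for DHT after DMSO, and RPA2 0.15 for the difference.

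A longer set of protein-coding names, ranks 6 to 15 per direction, was computed and then left out of the report after its dependence on the settings was known. Under the same alternatives 1107 of its values stayed within the limits, 401 moved and 12 reversed.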

Other observations

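The tests of a response to DHT, of mislabelled cells, of a lower baseline with Casodex, of a few dividing cells and of more dividing cells in the DHT culture were chosen after the results they measure had been seen. Those of cell quality, of transfer between libraries and of deeper DMSO libraries were written before.

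The androgen score was higher in DMSO-DHT than in DMSO-ethanol cells, and the ethanol cells had the higher mitochondrial share. If cell quality were the whole cause, the gap should narrow among cells of low mitochondrial share. Among cells with a share of at most 20%, 26 with DHT and 13 with ethanol, the DHT cell was higher in 92.9% of pairs, beside 87.6% over all cells, which argues against that. A response to DHT remains a candidate explanation: the androgen-induced list had a median of 1.13 in the 100k libraries, a separate set of libraries. With 1 sample per treatment, a difference between cultures, or between the blocks of title S numbers, that is not due to DHT was not tested.

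Some transcripts that were many times higher in the DMSO-DHT 100k library than in either ethanol 100k library were also seen in DMSO-ethanol cells. The Casodex-DHT 100k library was not used to choose them. Over a panel of 14 such genes chosen from the 100k libraries, the median percent of cells at 1 FPKM or more was 29.6 in DMSO-ethanol, 73.8 in DMSO-DHT, 20.3 in Casodex-ethanol and 17.9 in Casodex-DHT cells. At FPKM above 0 these medians were 68.5, 88.8, 37.8 and 41.1. The genes differed: TUBA3D, CCDC141 and ORM2 reached 1 FPKM in 0 of 27 DMSO-ethanol cells. Cell means were higher with ethanol than with DHT for UQCR11 (4.05 and 1.65 FPKM) and SEMA3C (9.91 and 5.18 FPKM). For SEMA3C the highest ethanol cell held 190 FPKM, and fewer ethanol than DHT cells reached 1 FPKM (22.2% and 42.5%). For UQCR11 these shares were 18.5% and 12.5%. The panel had median levels of 2.57, 36.7, 2.002 and 4.04 FPKM in the 100k libraries of these treatments. A candidate explanation was transfer of reads between libraries that share a title prefix. For 164 genes that were high in exactly 1 cell, 17.5% of the other cells with the same prefix had the gene above 0. In cells with the other prefix it was 16.7%, a ratio of 1.05. This argues against transfer within a prefix at a level visible from 1 source cell. It cannot exclude transfer of the panel genes, most of which reached 1 FPKM in many DMSO-DHT cells, nor transfer across prefixes. Deeper libraries of DMSO cells are argued against by 2370 other genes of low level, seen above 0 in a median of 37.0% of DMSO-ethanol and 35.1% of Casodex-ethanol cells, a ratio of 1.05. A few mislabelled cells, DHT cells carrying an ethanol label, are argued against as the whole cause. With no such transcripts in true ethanol cells, the 29.6% at 1 FPKM or more would need 10.8 DHT cells among the 27, of which 5.42 would be expected above the DHT median of the panel score, the mean of log2(FPKM+1) over the 14 genes. Of the 27 ethanol cells 0 lay above it, which allows up to 3. This counts only against the premise of no such transcripts. The DMSO-ethanol 100k library went against that premise too, with a panel median of 2.57 FPKM. Levels of the panel genes in that library ran from 0 FPKM for ORM2 to 13.7 for EAF2, with 13.1 for FKBP5. How much of the share in DMSO-ethanol cells such expression accounts for was not tested. For the excess over the 20.3% of Casodex-ethanol cells, 4.73 mislabelled cells would do, with 2.36 expected above the median, so as the cause of that excess they stay open. A lower baseline of androgen signalling with Casodex stays open. In the 100k libraries the lists fixed before the data were examined disagreed: for Casodex over DMSO with ethanol, the androgen-induced list had a median ratio of 0.047 (SD over genes 0.36) and the shared steroid receptor list −0.45 (percentile 1.07). The panel itself had 0.060 there, but it was chosen from these libraries. In cells the shared steroid receptor list had −0.73, and the panel had a median ratio of −0.53, with genes from −1.37 to 1.33. In cells the pretreatment and the title prefix cannot be told apart.

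The G2/M list had a median log2 ratio of 2.24 for DHT against ethanol in cells after DMSO and of −0.20 in the 100k libraries, or 0.21 with libraries rescaled to the same sum. A few dividing cells may account for the value in cells: it was 0.15 when the 3 cells of each group that scored highest on the other part of the genes were left out, and 0.22 when they were chosen by all 25 genes. The 3 highest cells held 86.3% of the G2/M FPKM in DMSO-DHT, 44.6% in DMSO-ethanol, 78.4% in Casodex-ethanol and 76.5% in Casodex-DHT cells. Those of DMSO-DHT had scores of 7.41, 7.07 and 5.21 beside a group median of 0.42, and the highest DMSO-ethanol score was 2.33. A rise of the size seen in cells was not found in the 100k libraries. The sign of the 100k median depended on the scaling, and the median gene was at −0.22 on the deposited scale. With 1 library per group, a smaller rise in dividing cells in the DHT culture stays open. The same list in Casodex against DMSO was lower in the 100k libraries with ethanol (−0.93) and with DHT (−1.10) under each scaling tried, and no explanation for that was tested.

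Cells with a title S number above 96 numbered 3, 16, 13 and 4 in the DMSO-ethanol, DMSO-DHT, Casodex-ethanol and Casodex-DHT groups. In DMSO-DHT they had a median of 4865 detected genes and a mitochondrial share of 41.04%, beside 6392.5 genes and 12.3% in the others. In Casodex-ethanol they had 5892 genes and 10.6%, beside 5457 genes and 14.1%. The meaning of the number is not stated. TMPRSS2 and ERG, the partners of the fusion in this line, were both at 1 FPKM or more in 29 of 40 DMSO-DHT cells, 10 of 27 DMSO-ethanol cells, 12 of 37 Casodex-ethanol cells and 8 of 28 Casodex-DHT cells. Of the DMSO-DHT cells 1 had TMPRSS2 alone, 7 had ERG alone and 3 had neither. Whether the overlap exceeds what the separate shares of these genes would give was not tested. The MT-TL1 gene had the highest FPKM in 62 of the cells, with up to 89.7% of the sum.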
